A study of Homo sapiens with 4 samples.

How the data were processed

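RNA sequencing was carried out on AMO1 cells, an established human plasmacytoma line used as a model of multiple myeloma, after 6 h with DMSO, the vehicle, or with periplocin. Periplocin is a cardiac glycoside, a class of plant steroid that blocks the sodium and potassium pump of the cell membrane. The vehicle was at 0.10% and periplocin at 0.2 mM as the labels give it; that dose is high for this drug class, and the unit was not checked here. Each group held 2 libraries, so 4 in all. Total RNA was sequenced as paired ends on an Illumina instrument, per the labels' protocols. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

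The authors deposited 1 table of TPM values (transcript abundances corrected for transcript length and scaled to the same sum in each library) for 37247 gene rows. GRCh38 and DESeq2 are named in the submitters' processing notes, with no role given. The aligner, the quantifier and the annotation are not given in the sources used here. The columns written PP were read as periplocin. TPM keeps no record of depth, so the number of reads behind each value is unknown and no counting interval can be given. Of the rows, 16015 were listed at 0 in all 4 libraries, and a value of exactly 0 can be a failed estimate, so such genes are described as listed at 0. Gene names and positions came from GENCODE 29 on GRCh38, which held 34620 of the identifiers, and 2627 identifiers had no place in its primary assembly. The rows were mostly protein-coding genes (19745) and processed pseudogenes (10087), with 7 rows of the long intergenic non-coding type, so non-coding RNA was not analysed here. Reads that fit near-identical genes, pseudogenes or overlapping genes can be split between rows, and strand use is not given in the sources used here, so values of such genes are uncertain.

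From these values, genes with a TPM of at least 1 in at least 2 of the 4 libraries were kept (12947). The values were transformed to log2(TPM + 1), and periplocin was compared with DMSO by the limma-trend test (limma 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05 on the adjusted p. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The fit had 2 residual degrees of freedom and borrowed 4.01 prior degrees of freedom from the other genes. An exact two-sided permutation test of a single gene with 2 against 2 cannot go below p = 0.333, so calls rest on limma's sharing of the spread between genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.

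The 33 gene lists, the tests and the rule for naming genes were fixed before the data were examined. Lists with at least 5 measured members (28 of the 33) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. With an estimated correlation camera uses only the 2 residual degrees of freedom of the fit, so a list could hardly pass. The rule named the 12 genes with the largest positive and the 12 with the largest negative fold change among called genes with a mean TPM of at least 5 in the higher group, no overlap between the groups and an ordinary gene symbol. MYC, IRF4, ATP1B1 and ATP1B3 were named whatever their result, as were up to 4 called members of each list with the largest change, or the 2 most abundant where none passed, giving 130 genes. Some genes that the rule selects are not reported here. How an ordinary symbol is recognised, including the removal of pseudogene types, was settled after the largest fold changes had been seen. Members of a list named as exceptions to its direction were chosen after their values were seen.

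The fit was tested on simulated tables of the same 12947 genes, in 20 runs with 200 genes changed in each. In all, 2 noise models were run, and the second was added after the first gave more false calls than the nominal rate. With each gene's noise set to the SD limma gave it, 10.0% of calls were false, and the fit recovered 26.9% of genes changed by 0.5 on the log2 scale, 83.1% of those changed by 1 and 99.7% of those changed by 2. With variances drawn from the prior that limma fitted, which matches the test's own assumption, 5.31% of calls were false, and recovery was 3.88%, 45.3% and 91.4%. The true share of false calls among the genes called here depends on which model is nearer to the libraries. It also depends on the share of genes that changed. The simulation changed 200 genes and shifted a list of 25, a far smaller share than the 29.3% of tested genes called here. These rates therefore do not carry over directly to this comparison. The 200 genes were drawn only from those above a minimum level, so the recovery does not cover low genes. Under both models a list of 25 genes shifted by 0.7 was called in 100% of runs, and 0.25% of unshifted lists were called. Those simulated genes were independent of each other, so the list result does not cover lists whose members vary together.

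In all, 22 alternative settings were run, 18 planned before the data were examined and 4 chosen after seeing the data. They changed the pseudocount (0.1 and 5), the filter (none, or a TPM of at least 5), the scaling (median-of-ratios size factors, quantile normalization, no mitochondrially encoded genes), the limma options (no trend, robust), the fold minimum (a log2 fold change of 1, or limma treat against a fold of 1.2), the libraries (each left out in turn), a replicate block, and the list test. The 4 added settings were protein-coding genes alone, median centring, and camera with an estimated correlation under size factors and under median centring.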

Results

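The series measured the transcriptome of AMO1 plasmacytoma cells after 6 h with the cardiac glycoside periplocin or with DMSO, in 2 libraries per group. The title of the series places the work in a study of how drugs that target the sodium and potassium pump lower c-Myc, and the comparison asks which transcripts differ between treated and vehicle cells. Depth is unknown because the values are TPM. A TPM of at least 1 was reached by 12892 and 12915 genes in the DMSO libraries and by 12357 and 12463 in the periplocin libraries. Across genes, the log2 values of the DMSO libraries correlated at r = 0.978 and those of the periplocin libraries at 0.976, against 0.941 to 0.947 between groups. These are correlations across genes, which are not independent replicates. Immunoglobulin transcripts took 10.01% ± 0.0680 (SD, n = 2) of all TPM with DMSO and 11.22% ± 0.192 (SD, n = 2) with periplocin.

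MYC, the gene for the transcription factor c-Myc (chromosome 8, 127735434 to 127741434 on GRCh38), fell from 605 ± 37.4 TPM with DMSO to 280 ± 2.88 TPM with periplocin (SD, n = 2), a log2 fold change of -1.11 with a standard error of 0.07 (limma adjusted p = 0.00218). Of the MYC antagonists in the MYC and MAX network, MXD1 (log2 fold change 1.23), MXD4 (0.80) and MXD3 (0.79) rose, and MXI1, named after its value was seen, did not pass (-0.02, limma adjusted p = 0.950). With no filter on low values MXD4 (limma adjusted p = 0.0507) and MXD3 (0.114) did not pass, nor did MXD3 without the trend (0.0701). Without periplocin replicate 1 neither MXD4 (0.0767) nor MXD3 (0.135) passed, and MXD4 did not without periplocin replicate 2 (0.0634). Of the 10 measured genes of that network 4 rose and 1 fell (6 and 1 with size factors). The counts adjusted over the list alone were 6 and 2, but the list test did not pass (camera adjusted p = 0.0815). IRF4, a transcription factor on which myeloma cells depend, fell from 129 ± 4.58 to 85.0 ± 3.96 TPM (log2 fold change -0.60, limma adjusted p = 0.00726). Without DMSO replicate 1 the MYC fold change was -1.17 with an adjusted p of 0.0976, and without DMSO replicate 2 it was -1.04 with an adjusted p of 0.0839, in fits where no gene passed.

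**Figure D1:**
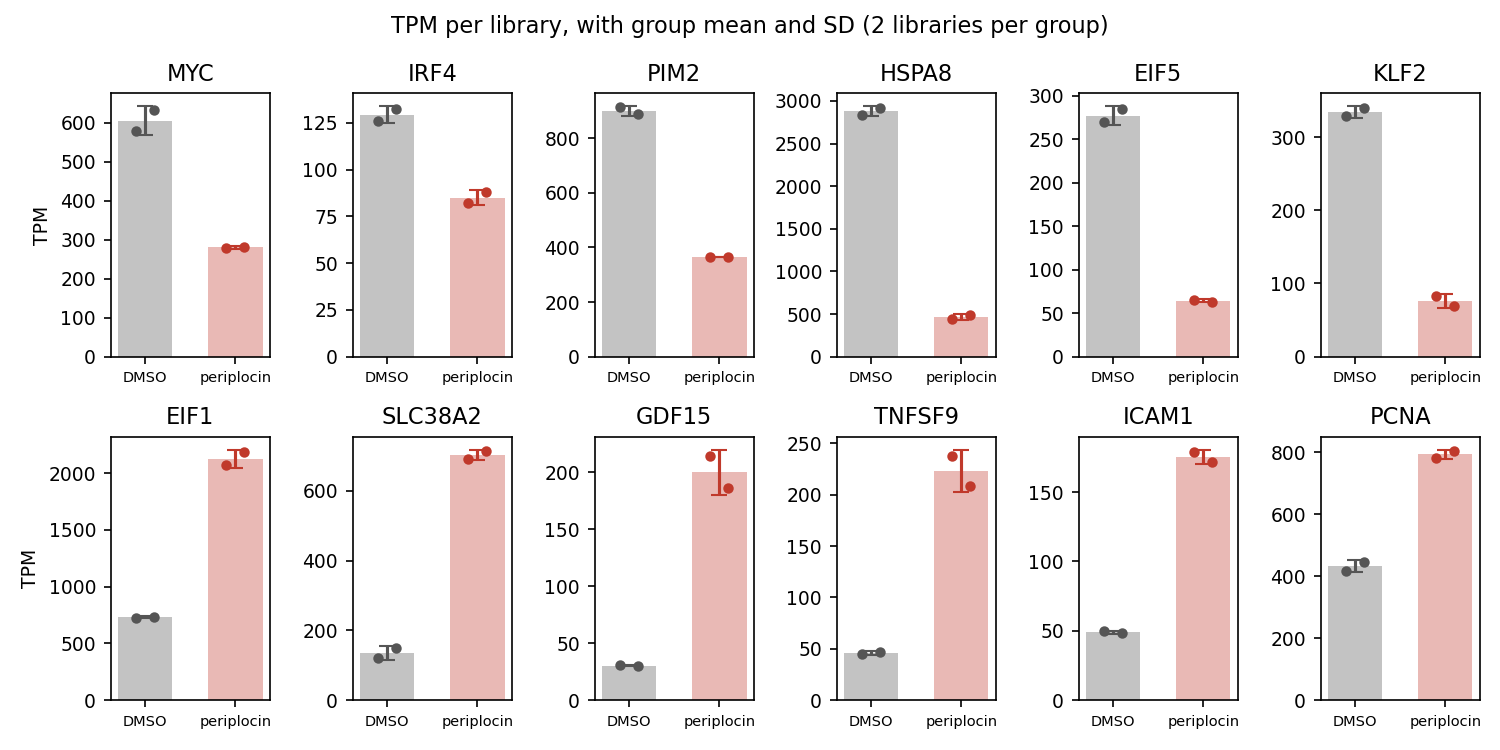
TPM of 12 genes in each library (points), with bars for the group means and error bars for the SD of 2 libraries; each vertical axis starts at 0 and has its own range. MYC averaged 605 TPM with DMSO and 280 TPM with periplocin, HSPA8 2879 and 462 TPM, and EIF1 731.5 and 2127 TPM.

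Across the transcriptome, 1352 of 12947 tested genes were higher with periplocin and 2443 were lower (limma, adjusted p under 0.05). Of these, 303 and 931 differed by at least 1 on the log2 scale. Among genes with ordinary symbols and a mean TPM of at least 5 in the higher group, the largest increases were in RAMACL, GDF15, ZBTB20, CREBRF, SLC38A2, TNFSF9, BBC3, EGR2, CCNG2, RFX1, ZBED6 and SPATA17. GDF15, a secreted stress cytokine, rose from 30.4 ± 0.242 to 200.4 ± 19.8 TPM (SD, n = 2; log2 fold change 2.68), and TNFSF9, the ligand of the 4-1BB receptor, from 46.0 ± 1.72 to 223 ± 20.9 TPM (2.25). BBC3, which encodes the cell death protein PUMA, rose from 11.9 ± 0.830 to 58.4 ± 5.61 TPM (2.21). RAMACL (3.18) closely resembles another gene and was listed at 0 in 1 DMSO library, and ZBTB20 (2.49) differed widely between the periplocin libraries, at 12.9 and 3.41 TPM. By the same rule the largest decreases were in SRPK3, CCDC183, BCAN, ADIRF, MRM1, LEMD1, HSPA8, IGLJ1, MKS1, UCP2, RIPOR2 and C2orf81. UCP2, a carrier of the inner mitochondrial membrane, fell from 189 ± 7.66 to 34.8 ± 7.37 TPM (-2.43). LEMD1 stood at 7.78 and 3.97 TPM with DMSO and was listed at 0 in both periplocin libraries, and it overlaps another gene. The short joining segment IGLJ1 (-2.49) shares sequence with its relatives. With no filter on low values 36 of the 130 named genes did not pass, among them RAMACL (limma adjusted p = 0.0629), ZBTB20 (0.101) and IGLJ1 (0.0520). The balance of higher to lower genes depends on the scaling: with median-of-ratios size factors 2012 genes were higher and 1745 lower, with quantile normalization 1757 and 1758, and with median centring 2117 and 1553. The median log2 fold change of all tested genes was -0.14 as deposited and -0.01 after size factors. No gene passed without DMSO replicate 1 or without DMSO replicate 2 (limma; 3925 and 4156 genes at an unadjusted p under 0.05, against 5585 with all libraries), while 522 were higher and 1142 lower without periplocin replicate 1, and 478 and 1077 without periplocin replicate 2.

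**Figure D2:**
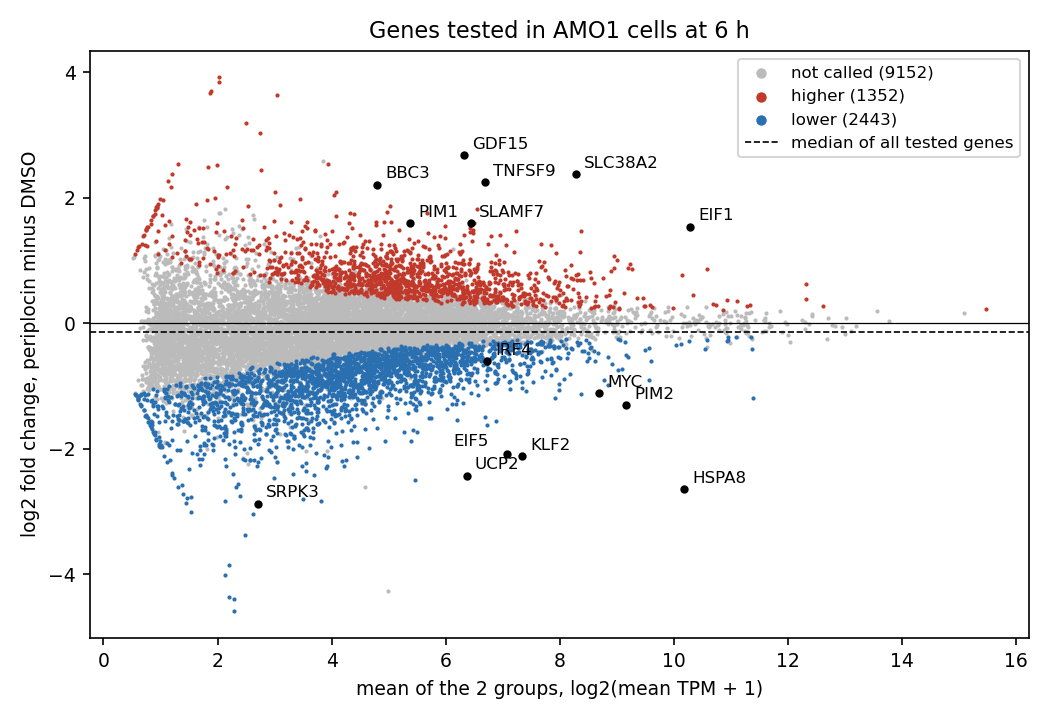
Log2 fold change of each tested gene (periplocin minus DMSO, vertical axis) against the mean of the groups as log2(mean TPM + 1) (horizontal axis), with 1352 higher genes in red, 2443 lower in blue and the rest in grey. The dashed line is the median of all tested genes, -0.14, and black points mark genes named in the text.

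More transcripts of MYC target genes were lower than higher. Of 53 MYC target genes 22 fell and 4 rose. With p adjusted over the list alone these were 29 and 4 (camera adjusted p = 0.00624, and adjusted p = 0.478 with an estimated correlation). After removal of a trend with GC content and transcript length, the list's mean fold change minus other genes was -0.147, against -0.203 as deposited. The list still passed after that removal (camera adjusted p = 0.0295). The p53, G1/S, immediate early and NF-kB lists then stood further from other genes than as deposited. The importin IPO4 (log2 fold change -1.51), the ribosome assembly factor RRP9 (-1.11), the arginine methyltransferase PRMT3 (-1.06) and AIMP2, a scaffold of tRNA synthetases (-1.03), fell. The 4 that rose were UNG (0.71), MCM4 (0.56), CDK4 (0.39) and NPM1 (0.31). Among 28 genes of RNA polymerase I and ribosomal RNA processing 10 fell and none rose. When adjusted over the list alone, 11 and 0 did, though the list did not pass (camera adjusted p = 0.100). UBTF, a factor of ribosomal RNA transcription, fell from 106 ± 0.475 to 46.2 ± 5.61 TPM, and POLR1E (-0.94), BOP1 (-0.62) and TAF1C (-0.59) fell. With size factors 5 of these 28 genes were lower and 1 was higher.

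The series concerns the making and breakdown of c-Myc protein, which these RNA values do not measure, but transcripts of both machineries were in the table. Of 34 translation factors 14 fell and 3 rose (4 higher and 6 lower with size factors; 16 lower and 3 higher when adjusted over the list alone; camera adjusted p = 0.151). EIF5, which acts in start codon selection, fell from 277 ± 10.9 to 64.4 ± 1.83 TPM (log2 fold change -2.09, limma adjusted p = 0.000911). EIF1, which acts in the same step, rose from 731.5 ± 6.84 to 2127 ± 80.8 TPM (1.54, limma adjusted p = 0.000911). EIF2S2 (-0.76) fell, as did EIF3C (-0.86), which has a near-identical copy. Of 78 cytosolic ribosomal protein genes 2 rose and 8 fell as deposited (0 and 1 when adjusted over the list alone; camera adjusted p = 0.225), and with size factors, which shift all genes of a library alike, 21 rose and 1 fell. The list passed camera as higher with size factors (adjusted p = 0.0176, and adjusted p = 0.648 with an estimated correlation) and with median centring (adjusted p = 0.0184, and adjusted p = 0.714 with an estimated correlation). RPL14 fell by 0.60. The falls of RPL11 (-0.41), RPL5 (-0.28) and RPL29 (-0.28) did not pass with size factors. Of 33 proteasome subunits 1 was higher and 3 lower (5 and 1 with size factors; 0 and 1 adjusted over the list alone; camera adjusted p = 0.877). PSMD4, a ubiquitin receptor, fell by 0.93 and PSMD7 rose by 0.31, and PSMC1 (-0.31) and ADRM1 (-0.29) did not pass with size factors. Of 22 genes for enzymes that act on MYC protein stability 7 rose and 3 fell. The counts adjusted over the list alone were 7 and 4 (camera adjusted p = 0.0815). The PIM kinases moved apart: PIM2 fell from 899 ± 17.9 to 364 ± 0.953 TPM (-1.30), while PIM1 rose by 1.59 and PIM3 by 0.99. The deubiquitinase USP37 rose by 0.99.

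The pump subunit ATP1B3 rose by 0.63, and ATP1B1 rose by 1.47 at the low levels of 0.160 and 2.26 TPM. Of 6 measured pump genes 2 rose and 1 fell, with the same counts adjusted over the list alone (2 and 0 with median centring; camera adjusted p = 0.365). Of 17 other genes of cation and volume transport 6 fell and 1 rose (6 and 3 with size factors). With p adjusted over the list alone these were 7 and 2 (camera adjusted p = 0.688), among them the volume-regulated channel subunit LRRC8D (-1.10), SLC8B1 (-0.999), the kinase STK39 (-0.90) and the potassium chloride cotransporter SLC12A4 (-0.85). Of 8 genes of the osmotic stress response 4 rose and none fell. When adjusted over the list alone, 4 and 1 did (camera adjusted p = 0.0546). SLC38A2, an amino acid transporter that cells use to take up osmolytes, rose from 136 ± 19.5 to 704 ± 15.3 TPM (2.37), the kinase SGK1 by 1.47, the osmotic transcription factor NFAT5 by 1.12 and the taurine transporter SLC6A6 by 1.05. Without DMSO replicate 2 the SLC6A6 fold change was 0.68.

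Of 23 p53 target genes 13 rose and 2 fell. The counts adjusted over the list alone were 13 and 3 (camera adjusted p = 3.55e-05, and adjusted p = 0.478 with an estimated correlation). GDF15 and BBC3 belong to this list, as do the death receptor TNFRSF10B (1.55) and the RNA-binding protein ZMAT3 (1.46). TP53I3 (-1.01) and PLK3 (-0.61) fell, but neither was called lower with size factors. Of 14 BCL2 family genes 6 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0551): besides BBC3, the death-promoting PMAIP1 (1.11) and BMF (0.94) rose, as did the survival gene BCL2 (0.97). Of members named after their values were seen, the survival gene MCL1 (0.87) and the death-promoting BAK1 (0.32) rose, and the death-promoting BIK (-0.53) fell. Of 23 immediate early genes 11 rose and 3 fell. With p adjusted over the list alone these were 12 and 4 (camera adjusted p = 0.00139, and adjusted p = 0.478 with an estimated correlation). EGR2 rose by 2.17 and GADD45B by 1.49, whereas the transcription factor KLF2 (-2.12) and the phosphatase DUSP5 (-1.62) fell. Of 14 NF-kB target genes 8 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00340, and adjusted p = 0.478 with an estimated correlation). ICAM1, an adhesion molecule, rose by 1.82, RELB by 0.92, NFKBIE by 0.89 and BIRC3 by 0.84. Of 22 genes of the amino acid and integrated stress response 7 rose and 2 fell (8 and 0 with size factors, where camera gave an adjusted p of 0.0199, and adjusted p = 0.508 with an estimated correlation). When adjusted over the list alone, 7 and 3 did (camera adjusted p = 0.0546), with CHAC1 (1.62), PPP1R15A (1.51), DDIT3 (0.96) and DDIT4 (0.84) higher.

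HSPA8, the constitutive HSC70 chaperone (chromosome 11, 123057489 to 123063230), fell from 2879 ± 61.1 to 462 ± 35.3 TPM (log2 fold change -2.64 with a standard error of 0.07, limma adjusted p = 0.000427). Of 15 heat shock genes 8 fell and 1 rose (6 and 3 with size factors). The counts adjusted over the list alone were 8 and 2 (camera adjusted p = 0.387), with HSPH1 (-1.12), HSP90AA1 (-0.56) and DNAJA1 (-0.55) among the lower ones. Of 22 genes of the unfolded protein response 9 fell and 1 rose, with the same counts adjusted over the list alone (7 and 2 with size factors; camera adjusted p = 0.225). The endoplasmic reticulum chaperones HSPA5 (-0.91) and CALR (-0.90) fell, as did CRELD2 (-1.25) and MANF (-0.84).

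**Figure D3:**
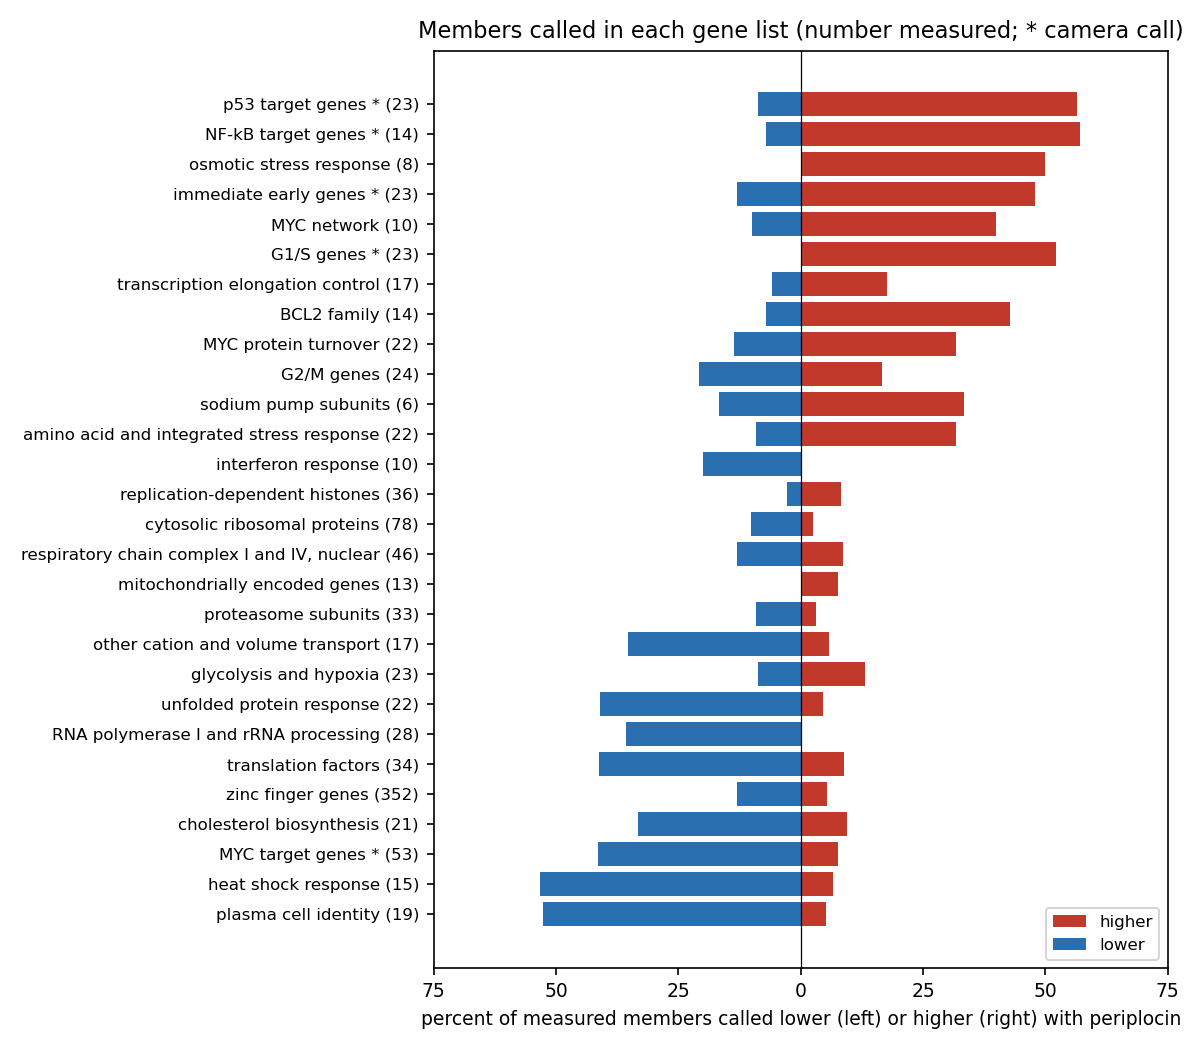
Percent of the measured members of each of 28 gene lists that were called higher (red, right) or lower (blue, left) with periplocin, with the number measured in brackets and a star for the 5 lists called by camera at the preset correlation. With an estimated correlation none of the 28 lists was called. In the p53 list 13 of 23 members were higher and 2 lower, and in the list of MYC targets 4 of 53 were higher and 22 lower; in the ribosomal protein, proteasome, G2/M and respiratory chain lists more members were lower than higher, and with size factors, which shift all genes of a library alike, more were higher.

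Of 19 plasma cell genes 10 fell and 1 rose, with the same counts adjusted over the list alone (7 lower and 2 higher with size factors; camera adjusted p = 0.155). The surface receptor FCRL5 (-2.13), cyclin D1 or CCND1 (-1.46) and PRDM1, a regulator of plasma cell fate (-0.98), fell, while SLAMF7, a surface antigen of myeloma cells, rose from 48.8 ± 1.44 to 149.5 ± 14.7 TPM (1.59). Genes of the G1/S step of the cell cycle rose in 12 of 23 cases and fell in none, and in 13 and 0 when adjusted over the list alone (camera adjusted p = 0.000113, and adjusted p = 0.478 with an estimated correlation): UHRF1 rose by 1.27, CDC25A by 0.89, CCNE1 by 0.72 and PCNA from 433 ± 20.3 to 793 ± 16.0 TPM (0.87). Of 24 G2/M genes 4 were higher and 5 lower (7 and 1 with size factors; 5 and 5 adjusted over the list alone; camera adjusted p = 0.127), with HMMR at -0.997, NUSAP1 at 0.82, CKS2 at 0.65 and CENPF at 0.55.

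The remaining lists did not pass camera, which compares a list with all other genes, so its direction can differ from the sign of the list's own median. For the interferon list the median was 0.07, the mean -0.17 and the direction up. For the ribosomal proteins the median was 0.01, the mean -0.02 and the direction up, and for the glycolysis list the median of -0.12 and the mean of -0.04 stood against a direction of up. For the respiratory chain list the median was -0.06 and the mean -0.09 with the direction up, and for the histones the median was 0.05 and the mean -0.05 with the direction up. Of 23 glycolysis and hypoxia genes 3 rose and 2 fell, with the same counts adjusted over the list alone (6 and 1 with size factors and with median centring; camera adjusted p = 0.857). The glucose transporter SLC2A3 rose by 1.48, VEGFA by 0.74 and ENO2 by 0.51, and ANKRD37 fell by 1.32. Of 21 cholesterol synthesis genes 7 fell and 2 rose as deposited, 3 and 3 did with median centring. With p adjusted over the list alone these were 10 and 2 (camera adjusted p = 0.372), with MVD (-1.05) and NSDHL (-0.78) lower, PMVK at -0.81 and SREBF2 (0.48) higher. PMVK did not pass with median centring. Of 17 genes of transcription elongation control 3 rose, among them BRD2 (0.62) and ELL (0.54), and 1 fell (HEXIM2, -1.25), with the same counts adjusted over the list alone (6 and 1 with size factors, 7 and 1 with median centring; camera adjusted p = 0.0815). Of 10 interferon response genes 2 fell and none rose (1 and 1 with size factors), 1 and 0 when adjusted over the list alone (camera adjusted p = 0.918): OAS2 (-1.22) and ISG15 (-0.57), the latter not passing with size factors. Of 352 zinc finger genes 46 fell and 19 rose as deposited, 31 and 31 with median centring, and 37 and 12 when adjusted over the list alone (camera adjusted p = 0.155). ZNF32 (-2.02), ZNF573 (-2.01), ZNF777 (-1.99) and ZNF45 (-1.75) fell. Of 36 replication-dependent histone genes 3 rose and 1 fell, 1 and 0 when adjusted over the list alone (camera adjusted p = 0.258), with H2BC11 at 1.13, H2BC12 at 0.63 and H1-2 at 0.42. Without DMSO replicate 2 the H2BC11 fold change was 0.68. These genes closely resemble one another. Of 13 mitochondrially encoded genes MT-ND2 rose (0.36), and none did when adjusted over the list alone (camera adjusted p = 0.918). Of 46 nuclear genes of respiratory complexes I and IV 4 rose and 6 fell (7 and 2 with size factors; 3 and 6 adjusted over the list alone; camera adjusted p = 0.918), with COX7B at 0.58, NDUFV3 at -0.67, NDUFA7 at -0.63 and NDUFB10 at -0.41, the last not passing with size factors.

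Few markers of other cell types passed the filter. Of 3 measured B cell markers none passed. FCER2 stood at 12.1 and 11.9 TPM and BCL6 at 1.02 and 2.43 TPM. Of 4 measured T and NK cell markers NKG7 fell from 3.20 to 0.482 TPM (-1.54), and none was called with size factors. CD4, named after its value was seen, stood at 58.8 and 50.0 TPM and did not pass. The 1 measured myeloid marker, CSF1R, stood at 0.792 and 1.19 TPM, and of 3 epithelial and stromal markers none passed, with KRT8 at 19.0 and 17.8 TPM and PECAM1 at 3.08 and 1.51 TPM. None of the snoRNA host genes was measured. These 5 lists were too small to test.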

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

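Protein-coding genes alone, median centring, and the estimated correlation with size factors or median centring were chosen after seeing the data; the other settings were planned. The MYC fold change kept its sign in every setting that gave one, from -0.94 with median centring to -1.17 without DMSO replicate 1, and passed in all but those without a DMSO library, where no gene passed. The range was -1.17 to -1.04 over the libraries left out, with the lone library assumed to vary like the other group, and the count of genes ran from 0 to 522 higher and from 0 to 1142 lower; fewer samples leave fewer degrees of freedom. No called gene was called with the other sign under any setting. The counts of higher and lower genes were 613 and 1026 with no filter on low values, where more genes were tested, 303 and 931 with a log2 fold minimum of 1 and 542 and 1115 with limma treat against a fold of 1.2, which are stricter by construction. Without the trend 876 genes were higher. Of the 130 named genes 36 lost their call with no filter, 24 without the trend, 29 without periplocin replicate 1 and 35 without periplocin replicate 2. Of those reported here, ZBTB20, MXD3, USP37, RPL11, RPL5, RPL29, PSMD7, PSMC1, ADRM1, SLC6A6, DNAJA1, CENPF, PMVK, ISG15, BRD2, H2BC11, H2BC12, H1-2 and MT-ND2 lost it in both, RAMACL, IGLJ1, ATP1B1, MXD4, BOP1, EIF2S2, SLC8B1, STK39, NFAT5, DDIT4, ANKRD37, VEGFA, HEXIM2, ZNF573, ZNF45 and NDUFV3 with no filter alone and HSP90AA1, ENO2, SREBF2 and NDUFB10 without the trend alone. Median centring, which shifts every gene by the same amount per library, gave 2117 and 1553. The replicate numbers are shared between the groups, but the deviations of same-numbered libraries correlated at 0.0324 and do not pair them; with a replicate block 1685 genes were higher and 2876 lower. The 5 list calls by camera became 8 with a pseudocount of 5, with no filter and with quantile normalization. They became 0 with an estimated correlation, alone or with size factors or median centring, which with 4 libraries is itself poorly known. The estimate for the p53 list (-0.0449) lay below the preset 0.01, yet its unadjusted camera p rose from 1.27e-06 to 0.0332. For the MYC targets (-0.0176) it rose from 0.0011 to 0.057. For the immediate early (0.0411), NF-kB (0.0780) and G1/S (0.248) lists the estimate was above the preset. Losing a call in this form therefore does not show that members vary together. With fry 18 lists passed, but fry asks whether a list moves at all rather than relative to other genes, so this is not the same count. Lists that passed camera elsewhere but not as deposited were RNA polymerase I (adjusted p = 0.0192 with no filter, 0.0181 with quantile normalization), translation factors (0.0300 and 0.00780 likewise), the BCL2 family (0.0350 with a pseudocount of 5, 0.0361 with no filter, 0.0414 with a TPM of at least 5, 0.0271 without periplocin replicate 2), osmotic stress (0.0350 with a pseudocount of 5, 0.0491 without DMSO replicate 2), integrated stress (0.0350 with a pseudocount of 5, 0.0199 with size factors, 0.0215 with median centring, 0.0470 with protein-coding genes alone, 0.0491 without DMSO replicate 2, 0.0244 without periplocin replicate 2), plasma cell genes (0.0419 with quantile normalization) and ribosomal proteins (0.0176 with size factors, 0.0184 with median centring). The cause was not tested for the other changes.

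Some lists not called as deposited changed the direction that camera or fry gave, which need not follow the sign of the value printed, the mean log2 fold change minus that of other genes. The interferon list, at -0.00203 as deposited against a camera direction of up, gave -0.0143 with a pseudocount of 5, -0.0870 with no filter, -0.165 with a TPM of at least 5, -0.00332 with size factors, -0.0398 with protein-coding genes alone, -0.00203 with median centring and with fry, and -0.0839 to 0.0799 over libraries left out. The respiratory chain list, at 0.0758 as deposited, gave 0.0164 with a pseudocount of 5, 0.0307 with no filter, 0.0488 with a TPM of at least 5, -0.0925 with quantile normalization, 0.0758 with fry and 0.0286 to 0.123 over libraries left out. The proteasome list, at 0.0587 as deposited, gave 0.0771 with size factors, 0.0587 with median centring and 0.0357 to 0.0817 over libraries left out. Mitochondrially encoded genes, at 0.0766 as deposited, gave 0.0962 with size factors, 0.0767 with protein-coding genes alone, 0.0766 with median centring and -0.0169 to 0.170 over libraries left out. Ribosomal proteins, at 0.150 as deposited, gave -0.00901 with quantile normalization and 0.150 with fry. Glycolysis, at 0.120 as deposited, gave 0.0285 with quantile normalization and 0.120 with fry. The log2 fold changes of 3 uncalled genes changed sign. FCER2, at -0.01 as deposited, gave 0.12 with size factors, 0.20 with quantile normalization, 0.15 with median centring, 0.00813 with protein-coding genes alone and -0.10 to 0.0742 over libraries left out. KRT8, at -0.10, gave 0.0433 with size factors, 0.0588 with quantile normalization and 0.0696 with median centring, and BCL6, at 0.65, gave -0.00131 to 1.29 over libraries left out.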

Other observations

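The 6 gene groups of the next paragraph were chosen after the gene results had been seen, and all 6 are given; the tests of technical explanations were written before the values that decide them, although the split of calls, the rows at 0 and the fall of HSPA8 had been seen.

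Of 76 measured mitochondrial ribosomal protein genes 39 fell and 4 rose as deposited (MRPL44, MRPL48, MRPS6 and MRPL42), 33 were not called, and 29 fell and 7 rose with size factors (camera adjusted p = 0.00479 over these 6 groups, and adjusted p = 0.348 with an estimated correlation). Of 20 cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA, 8 fell and 1 rose (5 and 4 with size factors; camera adjusted p = 0.321). The 1 that rose as deposited, CARS1, stood near the floor, at 0.0692 TPM with DMSO and 1.57 TPM with periplocin. LARS1 fell from 112 to 54.4 TPM and FARSA from 163 to 84.3 TPM. Of 7 CLK and SRPK kinases, which phosphorylate splicing factors, 4 rose and 1 fell (camera adjusted p = 0.152), with CLK1 at 0.78 and CLK4 at 0.82 on the log2 scale and SRPK3 at -2.87. Of 11 SR splicing factors 2 rose and 5 fell (3 and 3 with size factors; camera adjusted p = 0.851), with SRSF2 falling from 649 to 326 TPM and SRSF4 rising from 69.8 to 109 TPM. Of 16 histone demethylases 4 rose and 1 fell (camera adjusted p = 0.173), KDM3A from 24.7 to 53.1 TPM, and of 36 DNAJ co-chaperones 2 rose and 9 fell (5 and 4 with size factors; camera adjusted p = 0.352).

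More genes were lower than higher as deposited, 64.4% of calls. After median-of-ratios rescaling 46.4% of calls were lower (95% binomial interval 44.8% to 48.1%). That interval treats called genes as independent, which genes measured in the same 4 libraries are not. Median centring gave 42.3%, outside that interval. Median-of-ratios rescaling centres the bulk of genes, so the balance it gives was set by its construction. It does not test whether abundant transcripts took a larger share of TPM. Removing a trend with GC content and transcript length, known for 95.8% of tested genes, left 64.2% lower. The removal kept the mean of all genes (-0.16 before and after), so it could hardly change this balance and cannot decide the question. That trend held 3.64% of the variance of the fold changes of those genes, with an SD of 0.115 on the log2 scale. The 10 most abundant genes of each library took 15.12% ± 0.367 (SD, n = 2) of all TPM with DMSO and 16.25% ± 0.0485 with periplocin. That rise is too small by itself to give the median log2 fold change of -0.14. The scale explanation stays open for abundant genes beyond those 10, and the trend explanation stays open. A loss of many transcripts with periplocin stays open as well and was not tested, since nothing in these values fixes the amount of RNA per cell.

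In 15 rows the gene was listed at 0 in both libraries of 1 group and had a mean TPM of at least 5 in the other, and all 15 were called. All 15 had a pseudogene type, overlapped another gene or lay outside the primary assembly, against 32.6% of 3369 rows of similar level; the lower 95% bound of the odds ratio was 7.40 (Fisher's exact test, two-sided, p = 5.35e-08). These switches may reflect reads moved between near-identical or overlapping rows, and LEMD1 is one of them. A change in the genes themselves was not tested apart from this.

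The fall of HSPA8, at 2836 and 2922 TPM with DMSO and 437 and 487 TPM with periplocin, was set against loss of its reads to its pseudogenes. The 17 pseudogene rows together held between 0.244 and 1.30 TPM per library, and the log2 change of the summed TPM was at least 0.999 of that of HSPA8 in all 4 pairs of libraries, which argues against that explanation. After removal of the GC and length trend the fold change was -2.59 on the log2 scale. An effect of periplocin on HSPA8 RNA is a hypothesis that these tests leave standing, with 2 libraries per group.

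A further hypothesis was that transcripts without introns rise relative to spliced ones, as they might if splicing were slowed. Replication-dependent histones of the gene list and mitochondrially encoded genes were left out of this test. The histone gene H2BC12L (0.06), which is not on that list, and nuclear MTRNR2L genes such as MTRNR2L12 (0.02) stayed in. The median log2 fold change of the 135 other single-exon protein-coding genes was -0.29. It lay inside the interval from -0.36 to -0.13 that held 95% of 10000 draws of multi-exon genes matched on level and length. Without the 3 members that are on the immediate early list the median was -0.34. No such rise was seen in these genes. The 36 measured histone genes had a median of 0.05 and the 13 mitochondrially encoded genes -0.07, and neither was compared with matched draws.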
